A study of Mus musculus with 16 samples.

How the data were processed

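Tail DNA of a male parent, a female parent and 6 progeny was hybridised against DNA of a reference male from the same colony, on 16 Agilent mouse arrays, per the labels. Each animal was labelled once with Cy5 and once with Cy3. The sources describe this as the first screen of the family; a denser second screen and TaqMan assays named in the design text were not analysed here. Replicate numbers of the progeny are those in their names. The 2 arrays of an animal are a technical dye swap and were counted as 1 replicate, so the groups held 1 male parent, 1 female parent and 6 progeny.

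Images were quantified with Agilent Feature Extraction 10.7.1.1, per the file headers, and DNA was labelled under version 4.0.8 of the Agilent protocol, per the labels. The deposited scanner files give spot intensity per channel, already background-subtracted and dye-normalized by the linear method, per the file headers, and log10 ratios of Cy5 over Cy3. Probe positions are those of the files, on mouse build NCBI37. The deposited value table of the series holds log2 ratios whose scale, centring and direction are not given in the sources used here. Set against the scanner ratios, each of its columns had a correlation of at least 0.990 in size. In 8 of 16 columns the sign was turned, so that all columns read as reference over animal. Column medians lay between −0.00413 and 0.0148. A small further correction in it remains unknown, and the table was used only as an alternative.

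From the processed signals, log2 of Cy5 over Cy3 was taken for 966371 non-control spots, spots marked as outliers were dropped, each array was centred on its median, and spots of the same probe were averaged. No loess or quantile step was applied. Arrays with the animal in Cy3 had their sign turned so that all ratios are animal over reference. A further 36 probes without a place on a chromosome were left out. The number of dropped spots ran from 119 to 3047 per array, the latter in the array of progeny 5 with the animal in Cy3. That array was also outside the range set by the laboratory software, and its derivative log ratio SD was 0.235, against 0.154 in the least noisy array. Between 98.0% and 100.0% of spots were well above background in both channels, and median background-subtracted signals ran from 97.0 to 251 in green and from 105 to 300.2 in red. No array had saturated spots. Dye-swapped arrays of an animal, once oriented, correlated between −0.35 and −0.23 over all autosomal probes, and arrays of different animals in the same orientation correlated between 0.25 and 0.43, so a dye bias of each probe is shared by the arrays and turns its sign within an oriented pair.

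Intervals were called in each animal from the dye-swap mean. The score of an interval is the sum of its log2 ratios over the noise SD times the square root of its number of probes, the noise SD being a robust estimate from differences of neighbouring probes. An interval needed a score of at least 6, at least 3 and at most 1000 probes, and a mean of at least 0.25 in the same direction in the pair and in each array. Best scores were taken first. Overlapping intervals of the same direction were merged over animals. A region was present in an animal if both arrays reached 0.25, and absent if the mean stayed under 0.15. Progeny-only regions were present in at least 1 progeny with both parents absent, and regions in between were left undecided (165), while 14 met no class after merging. These rules were fixed before the data were examined. Controls repeated the calling with the sign of 1 array of each pair unturned, once as planned and once, chosen later, after removing the mean dye bias of the other 7 animals from each probe. On simulated data with the noise of progeny 2 and progeny 5, the caller recovered all implanted regions of 5 or more probes with shifts of 0.54, 0.92 and −0.92, and 90% of 3-probe regions with a shift of 0.54 in the noisier animal. A region rested on 1 probe, in a rule chosen after the data were seen, if in no animal it was called in the mean without the most shifted probe reached 0.25; in simulated regions of 3 probes this held for all with 1 shifted probe and for none with all 3 shifted. The caller also made 34 and 115 calls in that shuffled noise before anything was implanted.

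Probe tests used limma 3.58.1 in R 4.3.3 on dye-swap means of 947229 complete autosomal probes, with Benjamini-Hochberg adjustment. In simulated data the comparison of all animals with the reference recovered 66% of probes shifted by 0.30 and 98% of those shifted by 0.54. The comparison of progeny with parents recovered 0% and 26%. Transmission was tested with an exact binomial test and a Clopper-Pearson interval in scipy 1.17.1, with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0 under Python 3.11.15. Scan days were taken from the file headers: both parents shared a day, and the progeny were scanned in pairs on 3 other days. The planned fit with scan day as a fixed block was limited to days holding both generations, of which there were none. Scan day was fitted instead as a random block and, for all animals against the reference alone, as a fixed block, both chosen after the results were seen.

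Alternatives were normexp background correction with an offset of 50, the deposited value table, a filter on dim probes, other thresholds for score, mean and number of probes, no threshold per array, subtraction of a running median over 1000 probes, stricter merging, inclusion of X, leaving out regions resting on 1 probe, other limma designs, the mean over the X probes, and leaving out each animal. When an animal was left out, the interval calls of the others were kept and only merging and classing were repeated. The files used have median in place of mean signals, so normexp was run on medians. Per class, the text names all regions if there were 10 or fewer and otherwise the 10 with the highest score; regions of at least 10 probes outside that rule were chosen after their values were seen. The files do not pair probes with genes, and the gene table at hand is on another build, so no gene is named and the gene lists fixed beforehand (receptor, immune, lymphocyte, detoxification, DNA damage and other clusters) could not be applied.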

Results

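Genomic DNA from the tails of 8 C57BL/6 mice of a single family was compared with DNA of a reference male by array comparative genomic hybridization, in which test and reference DNA carry different dyes and compete for the same probes. The family held a male parent, a female parent and 6 progeny. Each animal was hybridised on 2 arrays with the dyes exchanged, which gave 16 arrays and 1 value per animal once the dye-swapped pair was averaged. The series title describes males kept under gamma-rays at 1 mGy per day for 400 days, whereas its design text calls the male of this family not irradiated, so the exposure of the male parent is stated in conflicting ways. An unexposed family was not analysed here, and no difference below can be assigned to irradiation. The arrays carried 950749 different probes, of which 950622 lay on the 19 autosomes with a median spacing of 2053 bp, 68 on X and 23 on Y. The scatter between neighbouring probes of the dye-swap mean ranged from 0.09 log2 units in progeny 2 to 0.12 in progeny 5, and the number of arrays, 2 per animal, limits the precision of every value.

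The X and Y probes were used first to check the labels and the direction of the ratios. The median over the X probes of the dye-swap mean lay 0.93 log2 units higher in the female parent than in the male parent, at 0.95 against 0.02. The medians of the single arrays differed by 0.89 with the animals in Cy5 and by 0.88 with the animals in Cy3. Her Y probes stood at −2.31, against 0.05 in the male parent. Among the progeny, the X level was −0.02 in progeny 1, −0.01 in progeny 2, 0.00 in progeny 3, −0.01 in progeny 4, 0.00 in progeny 5 and 0.93 in progeny 6. The Y level was −2.31 in progeny 6 and lay between −0.04 in progeny 1 and 0.05 in progeny 2 in the other 5 progeny. A doubling would be 1 on the log2 scale, so the arrays returned slightly less than a full doubling for the additional X of the female parent. The sex of the progeny is not in the labels. By both levels progeny 6 matched the female parent and the other 5 progeny matched the male parent. All further comparisons used autosomes only.

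**Figure D1:**
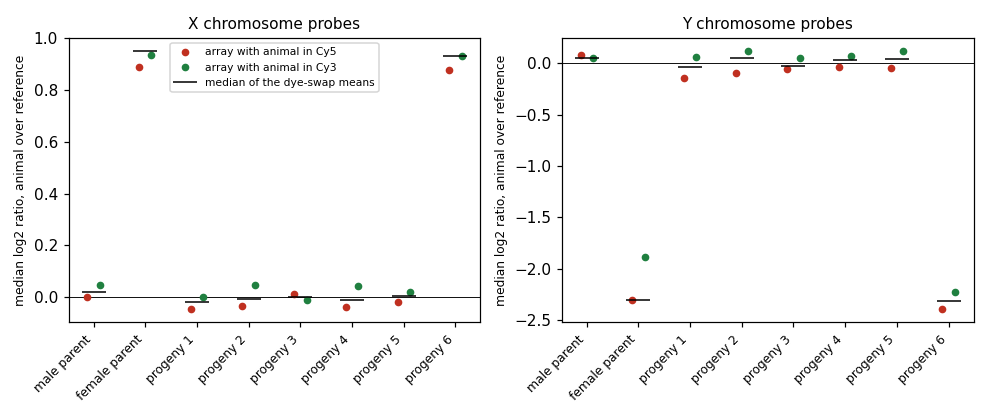
Median log2 ratio of each animal over the reference male for the X probes (left) and the Y probes (right). Points are the 2 dye-swapped arrays of an animal and bars the median of their mean, which lies at 0.95 for X in the female parent and at 0.93 in progeny 6.

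A difference carried by the reference mouse itself, or by the whole family, would appear in every animal, and 2 autosomal regions did so. On chromosome 4, positions 101110482 to 101270535 (NCBI37, 160 kb, 74 probes), all 8 animals lay above the reference. The level was 0.96 ± 0.03 in the male parent (SD of the 2 dye-swapped arrays, as for all region levels that follow) and 0.54 ± 0.02 in the female parent. Among the progeny it was 0.54 ± 0.01 in progeny 4, 0.93 in progeny 6, and 0.95 in progeny 1, progeny 2, progeny 3 and progeny 5. The chromosome 4 level thus differed within the family as well as from the reference. On chromosome 10, positions 33897213 to 33933441 (36.2 kb, 19 probes), all 8 animals lay below the reference, from −0.51 ± 0.03 in progeny 2 to −0.61 ± 0.01 in progeny 6, with −0.54 ± 0.02 in the male parent and −0.53 ± 0.01 in the female parent. Over all animals, windows of the same number of probes outside the called regions of 10 or more probes stayed between −0.10 and 0.17 for the chromosome 4 region and between −0.29 and 0.24 for the chromosome 10 region. Both regions were called in all animals under each of the 22 alternative settings. Those that left out an animal reused the same calls and could not lose either region.

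**Figure D2:**
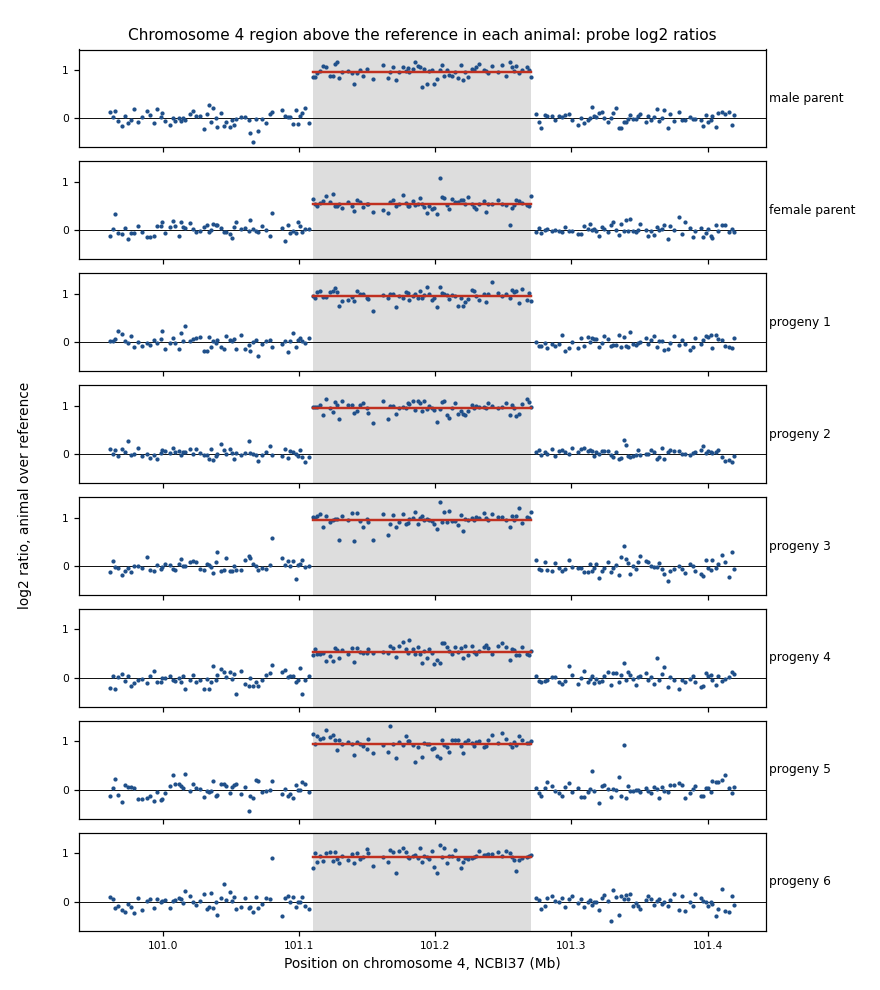
Log2 ratio over the reference of each probe (points) against position on chromosome 4, 1 panel per animal, with the called region shaded and its mean as a line. The female parent and progeny 4 stand at 0.54 and the other 6 animals between 0.93 and 0.96.

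Another stretch differed from the reference in all animals at a lower level. Over chromosome 14, positions 53387255 to 54393560 (112 probes), the animals lay between −0.22 in progeny 4 and −0.30 in progeny 1, and the male parent stood at −0.22 ± 0.04. Several arrays did not reach the threshold of 0.25, so the region was not counted among those in all animals, and it was classed as shared by a parent and progeny under 5 settings. Tested probe by probe with limma, the mean of the 8 animals differed from the reference at 268 of 947229 autosomal probes (adjusted p under 0.05 and at least 0.25 log2 units), 181 higher and 87 lower. Of these, 72 lay in the chromosome 4 region with a mean of 0.85, 18 in the chromosome 10 region with a mean of −0.55, and 54 in the chromosome 14 stretch with a mean of −0.36. A further 122 were isolated probes with no other such probe within 100000 bp, of which 107 were higher and 15 lower, and 2 lay close together on chromosome 2. The count was 168 without progeny 1, 178 with scan day as a fixed block, 643 without progeny 2 (550 of them higher) and 635 with single arrays and a dye term, and it leaves out the spread of the reference, which was a single mouse.

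The main question of the series was whether progeny carry copy number changes that neither parent has. The clearest such change was a loss in progeny 1 on chromosome 10, positions 73562961 to 73615416 (52.5 kb, 23 probes), with a level of −0.95 ± 0.07. Both arrays of this animal showed it, the smaller shift being −0.91. The male parent stood at 0.02 and the female parent at −0.02 over the same probes, and the other 5 progeny between −0.03 and 0.05. Its score of 45.5 exceeded the highest score of any region in the control sets, 14.9, and in progeny 1 no other window of 23 probes outside the called regions of 10 or more probes fell below −0.14 (949718 windows). The loss was called as progeny only under each of the 21 alternative settings that kept progeny 1, 2 of which left out a parent and so compared it with the other parent alone. Settings that left out another animal reused the calls of progeny 1 and could not lose it.

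**Figure D3:**
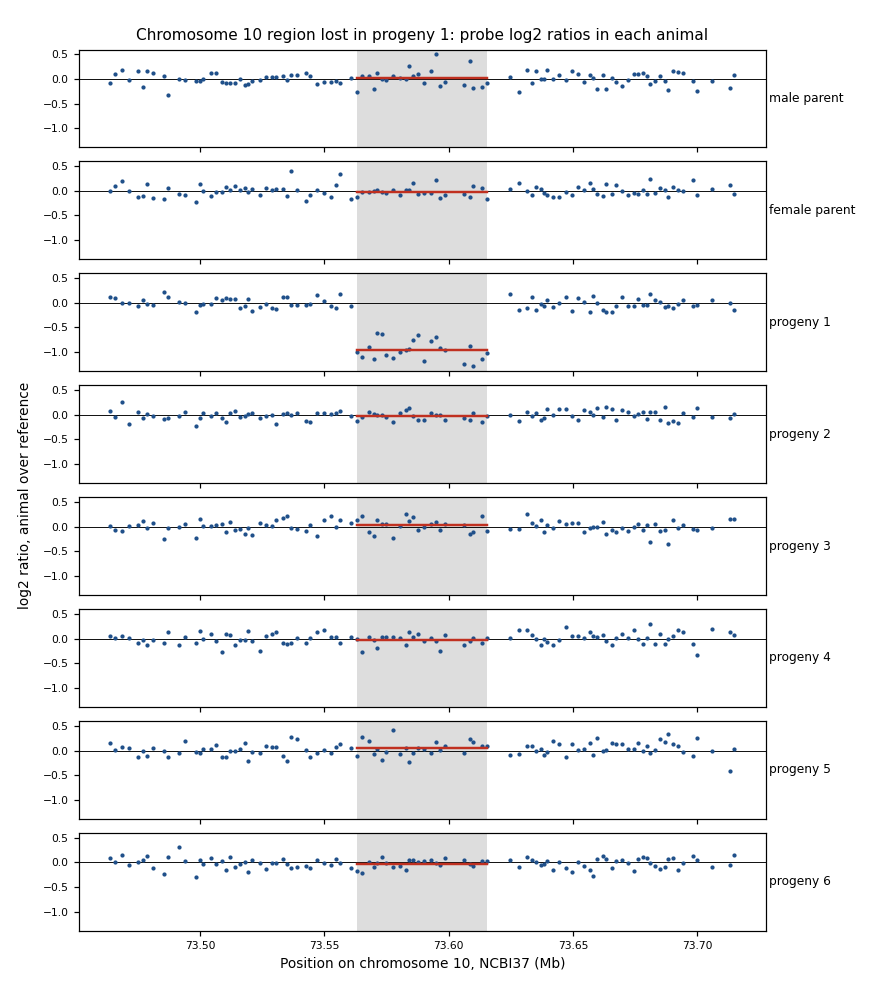
Log2 ratio over the reference of each probe (points) against position on chromosome 10, 1 panel per animal, with the region shaded and its mean as a line. The 23 probes of the region lie around −0.95 in progeny 1, and the means of the other 7 animals lie between −0.03 and 0.05.

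Progeny 5 held the other 2 progeny-only regions of at least 10 probes, both gains on chromosome 11. Positions 17202077 to 17249238 (15 probes) stood at 0.32 ± 0.06 and positions 23936290 to 23955272 (10 probes) at 0.30 ± 0.07, with both parents between −0.02 and 0.06 in the first and between −0.01 and 0.00 in the second. The highest other window in progeny 5 was 0.25 for 15 probes and 0.30 for 10 probes, so the second gain did not stand out from the rest of its genome. Without its most shifted probe the first stood at 0.24 and the second at 0.27. Both lay inside a longer stretch of chromosome 11, positions 13932416 to 28315621, over which progeny 5 averaged 0.12 ± 0.02. An array of progeny 5 was the noisiest of the 16. The first was called as progeny only under 18 and the second under 15 of 21 alternative settings. Settings that left out another animal reused the calls of progeny 5, so they could not lose either gain. Neither was called after normexp correction. The second was also not called with the deposited value table, a score of at least 8 or dye bias removed. With a running median subtracted, the first shrank to 3 probes and left the progeny-only class and the second was not called, and with a mean of at least 0.4 the first shrank to 5 probes and the second was not called.

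The remaining progeny-only regions were short. Of 383 in all, 193 were gains and 190 losses, and 380 held 3 to 9 probes. In 301 of these 380 the shift rested on 1 probe, the mean of the others staying under 0.25, and so it did in all 8 named next, whose level without that probe lay between −0.12 and 0.19. Those with the highest scores among them were 3-probe losses in progeny 2 on chromosome 8, positions 7087366 to 7092277, at −0.70 ± 0.57, and on chromosome 6, positions 66682889 to 66703427, at −0.59 ± 0.29. Progeny 6 had a loss on chromosome 8, positions 102897541 to 102903813, at −0.72 ± 0.42, and a gain on chromosome 5, positions 16894619 to 16901014, at 0.67 ± 0.11. Progeny 3 had a loss on chromosome 11, positions 83881092 to 83884780, at −0.66 ± 0.14. Progeny 4 had gains on chromosome 1, positions 187610357 to 187614315, at 0.69 ± 0.17, and on chromosome 7, positions 6047238 to 6053590, at 0.68 ± 0.21. Progeny 2 also had a loss on chromosome 10, positions 28719317 to 28725772, at −0.49 ± 0.24.

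By their number, progeny-only regions this short were not told apart from noise. With the sign of 1 array of each pair left unturned, where true copy number differences cancel, 50 regions were progeny only, and 351 were when the dye bias of each probe was also removed. The noise SD that divides the score was 0.134 to 0.173 in the former and 0.093 to 0.132 in the latter, against 0.085 to 0.125 in the dye-swapped pairs, so the former counts are not at equal noise. Without regions resting on 1 probe, 81 were progeny only, against 20 and 83 in these controls. Over all classes the dye-swapped arrays gave 790 regions, 489 gains and 301 losses, against 209 and 519 in these controls. The controls held 32 and 237 gains and 177 and 282 losses, so the excess over the latter control lay mostly in gains. Its cause was not tested. Of regions with at least 10 probes there were 8, against 5 and 0 in the controls. The progeny-only count ran from 5 with at least 10 probes, and 48 after normexp correction, to 966 without a threshold on each array, and the count over all classes from 11 with at least 10 probes to 1781 with a score of at least 5.

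Regions shared by a parent and progeny, the candidates for transmitted differences, numbered 44, with 27 gains and 17 losses. The balance depended on the setting: there were 4 gains and 10 losses after normexp correction, 3 and 13 with a score of at least 8, 2 and 7 with a mean of at least 0.4, and 3 and 8 with at least 5 probes, but 37 and 17 with a score of at least 5, 105 and 48 without a threshold on each array, and 25 and 4 without progeny 6. In 36 of the 44 the shift rested on 1 probe, which left 6 gains and 2 losses. Losses present in the female parent and progeny 6 made up 12 of the 44, and 10 of these 12 rested on 1 probe. The deepest lay on chromosome 3, positions 25417435 to 25432738 (3 probes), at −1.63 ± 0.12 in the female parent and −1.56 ± 0.17 in progeny 6, while the male parent stood at −0.02 and the lowest of the other progeny at −0.06. Without the most shifted probe it still stood at −1.32 and −1.24. The next 6 losses each came from 1 low probe, and their other probes averaged between −0.09 and 0.05 in both animals. On chromosome 6, positions 104236953 to 104242812 (4 probes), the female parent and progeny 6 stood at −0.69 ± 0.21 and −0.67 ± 0.24, and on chromosome 3, positions 132546474 to 132551005 (4 probes), at −0.60 ± 0.04 and −0.50 ± 0.08. On chromosome 11, positions 112961382 to 112965298, they stood at −0.68 ± 0.01 and −0.65 ± 0.03, and on chromosome 16, positions 40849337 to 40854519, at −0.65 ± 0.23 and −0.53 ± 0.17. On chromosome 9, positions 35853071 to 35857969, they stood at −0.55 ± 0.06 and −0.70 ± 0.06, and on chromosome 5, positions 123592752 to 123603094, at −0.36 ± 0.08 and −0.38 ± 0.11. These animals also had the X and Y levels that stood apart from the other 6.

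The other 3 high-scoring shared regions were each present in 3 or 4 animals. A gain on chromosome 13, positions 95703166 to 95712034 (5 probes), was present in the male parent at 0.40 ± 0.09, progeny 1 at 0.46 ± 0.11 and progeny 6 at 0.37 ± 0.01, and the lowest animal stood at 0.20. A single probe high in all 8 animals carried it, and the other 4 averaged between −0.08 and 0.08. A loss on chromosome 9, positions 74328400 to 74335188 (4 probes), was present in the male parent at −0.50, progeny 1 at −0.39 ± 0.05 and progeny 6 at −0.31 ± 0.08, again on 1 probe, without which these animals stood at −0.08, −0.01 and −0.01. A gain on chromosome 4, positions 22044889 to 22048379 (3 probes), was present in the female parent at 0.56 ± 0.04 and in progeny 1, progeny 3 and progeny 5; without the most shifted probe it stood at 0.39, 0.09, 0.12 and 0.42. A longer gain on chromosome 8, positions 102125282 to 102253497 (46 probes), stood at 0.26 ± 0.03 in the female parent and 0.28 ± 0.03 in progeny 6, and at −0.01 in the male parent. It was left undecided because an array of the female parent gave 0.24, just under the threshold, and it was classed as shared with the deposited value table, without a threshold on each array and with dye bias removed. The other progeny lay between −0.025 in progeny 1 and −0.0015 in progeny 4. The gain was thus seen only in the animals whose X and Y levels stood apart. Whether it was transmitted or follows the sex chromosomes was not tested. The shared count was 8 without the female parent, 29 without progeny 6 and 153 without a threshold on each array, and the controls held 39 and 9 such regions.

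Regions present in a parent and in no progeny numbered 182, where present means a mean past the threshold on both arrays. Of these, 181 had 3 to 9 probes and 146 rested on 1 probe. The controls held 34 and 110 parent-only regions, and without regions resting on 1 probe there were 36, against 12 and 19. Of the 10 with the highest scores, 9 were in the female parent. The gain on chromosome 6, positions 51194011 to 51198300, reached 0.93 ± 0.94 and that on chromosome 13, positions 51234150 to 51236760, reached 0.74 ± 0.66, so the dye-swapped arrays disagreed on their size, and without the most shifted probe they stood at 0.01 and 0.30. Her other gains lay on chromosome 12 (positions 44667319 to 44672027, 0.71 ± 0.36, and 37762901 to 37769146, 0.65 ± 0.54), chromosome 14 (9658228 to 9669393, 0.70 ± 0.13, and 105773526 to 105778050, 0.59 ± 0.37) and chromosome 15 (36109621 to 36112969, 0.59 ± 0.43). Her losses on chromosome 16, positions 38042231 to 38051285, and chromosome 4, positions 114579464 to 114587633, stood at −0.39 ± 0.04 and −0.47 ± 0.04, with progeny 6 at −0.22 and −0.31. The caller also found both in progeny 6, where 1 array stayed under the threshold, and both rested on 1 probe. The male parent had a gain on chromosome 3, positions 58952549 to 58956471, at 0.76 ± 0.71. The only such region of at least 10 probes lay on chromosome 14, positions 26812320 to 26953407 (11 probes), at 0.27 ± 0.02 in the male parent. The caller also found it in progeny 3, at 0.24, where 1 array stayed under the threshold. It rested on 1 probe, without which the male parent stood at 0.20. All other animals were also above the reference there, the female parent at 0.19 and the progeny between 0.14 and 0.24, the highest other window of 11 probes in the male parent reached 0.25, and the region kept its class under 16 of 22 alternative settings. It was not called under 4 of them, and without the male parent a region of 4 probes there was called in progeny.

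A difference carried on 1 of a parent's 2 chromosomes should reach about 1 in 2 progeny. The regions found in 1 parent and absent in the other were present in far fewer progeny, but they cannot show how carried differences were transmitted. Most of them are short, and the control without dye bias gave 90 such regions against 133 here, so many may be noise. The chromosome 4 region above the reference in all animals was not among them, since both parents had it. Over 133 such regions, counted once within 5 Mb, a region was present in 28 of 798 combinations of region and progeny, which is 3.51% (95% exact interval 2.34% to 5.03%; 2-sided exact binomial test against equal shares, p = 4.6e-189). In the control without dye bias, where true differences cancel, the value was 8 of 540, 1.48% (same test, p = 9.6e-146). The test thus rejected equal shares there too, so its p-value cannot decide whether carried differences were transmitted. The share was 1.94% without progeny 6 and 3.03% (6 of 198) without regions resting on 1 probe. The test treats regions as independent, although many may be noise. The chromosome 4 region, left out of this share, did differ within the family. It stood at 0.54 in the female parent and progeny 4, and between 0.93 and 0.96 in the male parent and the other progeny. Scaled to the X difference of the parents, 3 copies against 2 would read 0.54 and 4 against 2 would read 0.93.

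No autosomal probe passed the threshold for a difference between progeny and parents as groups. With limma, 0 of 947229 probes reached an adjusted p under 0.05 for the 6 progeny against the 2 parents, while 42838 had an unadjusted p under 0.05. The smallest adjusted p was 1.00. A change carried by a single animal, such as the chromosome 10 loss of progeny 1, is not what this contrast detects, and in simulated data it found 26% of probes changed by 0.54, 78% of those changed by 0.92 and 94% of those changed by −0.92, with 8 false calls. The count was 203 without the male parent (29 higher and 174 lower in progeny) and 21 without the female parent, where the remaining parent is assumed to vary like the progeny. Both parents were scanned on a day of their own, so scan day and generation cannot be told apart, and with scan day as a random block the count was also 0.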

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

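The tests of explanations in this part were all chosen after the results were seen; the region levels and the X and Y levels come from planned measurements. A progeny is listed here where its gap to the nearest other progeny took up most of the range of the 6. This was looked at for 43 series of values, and chance alone marks about 5% of such series; 17 were marked, many of them in regions picked because a progeny differs.

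The loss on chromosome 10, positions 73562961 to 73615416, set progeny 1 at −0.95, apart from the other 5 progeny. The tables argue against a chance run and against a dye effect or faulty array. A chance run of noisy probes would need control regions of like score, and the highest control score was 14.9 against 45.5. A dye effect or a faulty array would show in 1 orientation, but the smaller shift of the arrays was −0.91. Neither parent was seen to carry the loss in tail DNA, the lower parent standing at −0.0221. This is no separate test, since the region was classed as progeny only by that same absence in both parents. A loss that arose in a parental germ cell or in progeny 1 itself may account for it. Scaled to the X difference, 1 copy against 2 would read −0.93. The level of −0.95 thus argues against a loss of 1 copy in only a minor share of the tail cells. A parent mosaic in the germ line but not in the tail stays open. Without an unexposed family no effect of irradiation was tested.

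Progeny 6 stood apart in 7 of the shared losses: −1.56 on chromosome 3 at 25417435, −0.50 on chromosome 3 at 132546474, −0.38 on chromosome 5, −0.67 on chromosome 6, −0.70 on chromosome 9, −0.65 on chromosome 11 and −0.53 on chromosome 16. Its X level of 0.93 and Y level of −2.31 also stood apart. Of all losses shared by the female parent and progeny 6, 12 on 9 chromosomes, none was present in the other 5 progeny (counted once within 5 Mb, 0 of 55 combinations, upper 95% exact limit 6.49%), which random transmission of autosomal losses does not allow, and the control sets gave at most 3 losses shared by a parent and 1 progeny alone. Outside called regions, 20 single probes were below −0.4 on both arrays in the female parent and in progeny 6, against at most 6 with any other progeny. Of the 12 losses, 10 rested on 1 probe. A candidate explanation is that these probes also bind sequence on Y, which stood at −2.31 in both animals. X stood above the reference in both, at 0.95 in the female parent and 0.93 in progeny 6. Binding to X would therefore give gains and not losses. Sequence matching was not possible here.

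The remaining values are given without explanation. Progeny 4 stood apart from the other progeny on chromosome 4, positions 101110482 to 101270535, at 0.54, which was also the level of the female parent. Progeny 2 stood apart at −0.70 on chromosome 8, positions 7087366 to 7092277. Progeny 6 stood apart at −0.72 on chromosome 8, positions 102897541 to 102903813, and at 0.28 in the 46-probe gain on chromosome 8. The female parent stood at 0.26 in the same 46-probe gain. Progeny 5 stood apart in both chromosome 11 gains, at 0.32 and 0.30, and in probes without a value, of which it had 2885.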

How the results depend on the processing

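Alternatives with at least 10 probes, with dye bias removed, without regions resting on 1 probe, with scan day as a random or fixed block or with the mean over the X probes were chosen after the results were seen; the others were planned. The 2 regions in all animals were found under each setting, with 3 counted under stricter merging and without progeny 4. In the order all, progeny-only and shared, region counts (main 790, 383 and 44) were 127, 48 and 14 with normexp; 140, 61 and 16 with a score of at least 8; 154, 72 and 9 with a mean of at least 0.4; 187, 104 and 11 with at least 5 probes; 1737, 966 and 153 with the mean of the pair alone; 161, 81 and 8 without regions resting on 1 probe; and 11, 5 and 1 with at least 10 probes. They were 272 and 104 (all, progeny-only) with dim probes left out and 1781 and 945 with a score of at least 5. Gains made up 61.9% of regions in the main setting, 76.1% with dim probes left out and 52.6% with a mean of at least 0.4. Leaving out each animal gave 653 to 742 regions, 264 to 515 progeny-only regions, 8 (without the female parent) to 44 shared regions and a transmitted share of 1.94% to 4.15%. With at least 10 probes the transmitted share was 16.7% (1 of 6, exact binomial p = 0.219), no longer past the threshold because a single region was left. Probes differing from the reference numbered 635 with single arrays, 178 with scan day as a fixed block and 168 to 643 (without progeny 2) with an animal left out; those differing between generations ran from 0 to 203 (without the male parent). The X difference was 0.86 ± 0.19 (SD of the 2 dye-swapped arrays) with normexp, whose arrays thus disagreed, and 0.917 ± 0.0357 as the mean over the X probes. The cause of these changes was not tested, except where a threshold itself admits fewer or more regions. The X difference rests on the parents alone, and transmission needs both, so neither was computed without a parent. The generation contrast was not fitted with scan day as a fixed block, since no day held both generations. Of the 8 regions of 10 or more probes, normexp lost 3, both chromosome 11 gains of progeny 5 and the gain at 26812320 on chromosome 14, and leaving out dim probes lost the last of these.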

Other observations

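The tests in this part were all chosen after the results were seen. Progeny 5 showed low-level gains over long stretches of 3 chromosomes that the interval caller, with its threshold of 0.25, was not built to find. Over chromosome 11, positions 13932416 to 28315621 (14.4 Mb, 4900 probes), it averaged 0.12 ± 0.02 (SD of the 2 dye-swapped arrays), while the other 7 animals lay between −0.01 and 0.01. Over the whole of chromosome 3 (61220 probes) it averaged 0.038 ± 0.023, and over chromosome 10, positions 59741467 to 129933049 (70.2 Mb, 28280 probes), 0.040 ± 0.007. Divided into 20 equal blocks, progeny 5 ranged from 0.107 to 0.140 on the chromosome 11 stretch, from 0.0348 to 0.0416 on chromosome 3 and from 0.0332 to 0.0493 on the chromosome 10 stretch. The scores were 61.4 for chromosome 3, 58.0 for the chromosome 11 stretch and 42.2 for the chromosome 10 stretch. The next highest in any other animal was 25.03, and the highest in the control with 1 array unturned was 12.1. Larger shifts against the median of the other animals than the 0.037 and 0.038 of chromosomes 3 and 10 occurred among the best intervals of the other animals only over 400 probes each, in progeny 4 (−0.087) and the female parent (−0.064) across the chromosome 4 region and in progeny 1 (−0.076) across its chromosome 10 loss.

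A noisy array was weighed first, since progeny 5 had the noisiest of the 16: in 3 of 3 intervals even its smaller array lay above all 14 arrays of the other animals, and that argues against it. Slow waves of this DNA extract would also move other chromosomes, but the largest shift in its best interval on any of the other 16 was 0.00693 in size, against 0.038 for the smallest of the gains. A candidate explanation is that a share of the tail cells of progeny 5 carried extra copies of these stretches; scaled to the X difference, the levels correspond to 19.4, 5.74 and 6.00 additional copies per 100 cells for chromosomes 11, 3 and 10, or to 20.4, 6.02 and 6.28 with the mean X difference of the single arrays, 0.887. Whether DNA from another source was mixed in was not tested, and no link to the exposure can be drawn from 1 animal.

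Scaled to the X difference of the parents, 3 copies against 2 would read 0.54, 4 against 2 would read 0.93, 1 against 2 would read −0.93 and 2 against 3 would read −0.54. With the mean X difference of the single arrays, 3 copies against 2 would read 0.52 and 4 against 2 would read 0.89. The chromosome 4 region stood at 0.54 in the female parent and progeny 4 and between 0.93 and 0.96 in the other 6 animals. The chromosome 10 region below the reference in all animals stood between −0.61 and −0.51, and the loss of progeny 1 at −0.95.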
